A study of Gallus gallus with 6 samples.

How the data were processed

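Genomic DNA from blood of 6 adult chickens was compared by array comparative genomic hybridisation, a method in which test and reference DNA compete for the same probes. There were 3 breeds, white Leghorn, Cobb broiler and Dou, with 1 female and 1 male of each, and 1 array per bird. Per the labels, the test DNA carried Cy5 (red) and the reference, DNA of a female Dehong chicken, carried Cy3 (green) on all 6 arrays. There was no dye swap and no repeat hybridisation. Per the labels' protocols, the DNA was cut with AluI and RsaI and labelled with an Agilent genomic DNA labelling kit. Each bird counted as 1 sample, and nothing in the labels stated whether birds of a breed were related.

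The deposited scanner files came from Agilent Feature Extraction 10.7, per the submitters' processing notes. Per the file headers, the processed red and green intensity of each spot had been background-subtracted, detrended over the slide and scaled with linear dye normalisation, without lowess. The deposited files also gave the raw median intensity of each spot and its local background, and the log10 ratio of the processed red and green signals, per the file headers. Spot flags for signal well above background, saturation and outliers were read from the same files. The deposited value table of the series was the scanner's log10 ratio, with a largest absolute difference of 0 on each array. Its column medians were 0.00491, -0.00296, -0.00879, -0.00480, 0.00311 and -0.00629 for the female and male white Leghorn, the female and male Cobb broiler and the female and male Dou, so it was not centred.

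Probe positions were those of the chicken build galGal3 in the file headers. Of 414561 non-control spots, 450 had no genome position and were left out, and 411493 distinct probes remained after spots of the same probe were averaged. They comprised 376844 probes on 28 autosomes, 25612 on Z, 187 on W and its unordered part, and 7998 on unplaced sequence. Median spacing on the autosomes and Z was 2234 bp. Between 189 and 423 outlier spots per array were left out, and saturated spots were kept.

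The log2 ratio of processed red over green signal was computed per probe and centred on the median of all mapped probes of its array, without loess or quantile normalisation. Positive values mean more signal from the test bird than from the Dehong female. Between 99.8% and 99.9% of non-control spots were well above background in each channel. Where probes were not well above background in any male, a bound was computed with each such signal set to the higher of its own value and the lowest signal well above background on that array, and written as at least so many fold. The SD of the probe noise was estimated from differences between neighbouring probes of each array. It was 0.183 and 0.177 in the female and male white Leghorn and 0.235 and 0.165 in the female and male Cobb broiler. In the female and male Dou it was 0.168 and 0.161. Estimated on the difference between the 2 birds of a breed, it was 0.102 in white Leghorn, 0.119 in Dou and 0.248 in Cobb broiler. In white Leghorn and Dou this was below either bird's value, so part of the estimate was probe-to-probe signal common to both arrays. The number of arrays limits the precision.

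Each array was segmented by optimal partitioning of its ordered log2 ratios, with a penalty of 18 per breakpoint, which corresponds to a z score of 6. Single probes more than 3 noise SDs beyond both neighbours were first set to the median of 5 probes. A gain or loss call needed at least 5 probes and a segment mean at least 0.4 from 0. Z was centred on its own median in each array, so that whole-chromosome sex dosage gave no call, and W and unplaced sequence were not segmented. Calls that overlapped by at least 1 base were merged into copy number regions.

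Means of 10 consecutive probes formed 37671 autosomal, 2561 Z and 18 W windows. These were fitted with limma 3.58.1 under R 4.3.3, with breed and sex as terms and 2 residual degrees of freedom, moderated by eBayes with 3.56 prior degrees of freedom. Sex was tested over all windows, breeds over autosomes and Z, and the mean of the 6 birds over autosomes with limma's treat at a log2 threshold of 0.2. P-values were adjusted by Benjamini-Hochberg and counted below 0.05, two-sided. Chromosome medians were compared between 3 males and 3 females by an exact two-sided permutation test, whose smallest p is 0.1. Resemblance within breeds was tested exactly over the 15 ways to form 3 pairs, one-sided, with a smallest p of 0.0667. Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

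The segmentation was tested on simulated data: segments of 5 probes at 0.58 were recovered in 73.3% of cases, at 1 in 90.1%, and segments of 10 probes in 96.4% and 100%. Between 2 and 7 false calls were made per simulated array. Whether false calls are as few among the calls of the real birds was not tested. Segments were inserted at 0.58 and 1 only, so recovery nearer the call threshold was not measured. In windows simulated from each window's own mean and residual spread, the breed test recovered 0% of the windows changed by 0.3 in Dou, 23.4% at 0.6 and 62.9% at 1, among 40232 windows tested. Among 40250 windows, the sex test on autosomes recovered 75.8%, 94.5% and 98.5% at these sizes. It also called 112 of 37471 unchanged autosomal windows, because the many Z windows with a true difference relax the adjusted threshold for all windows. To see how many probes an even change would move, the effect of each autosomal window lower in males was added to the centred probe differences of a random autosomal window, in 1000 draws.

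Each slide held the 2 arrays of 1 breed. The white Leghorn slide was scanned on another day than the Cobb broiler and Dou slides, which shared a day. Breed and slide therefore cannot be told apart in comparisons between breeds. Each slide held a female and a male, so in the sex test the breed term was also the slide block.

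The regions and runs named by position followed a rule fixed before the data were examined. It took the 8 regions with the largest absolute mean among those called in at least 2 birds, the 5 longest, up to 8 called in all 6 birds, and up to 5 per breed called in both birds of that breed and in no other. It also took, per test, up to 5 runs of at least 2 adjacent passing windows in each direction. Gene annotation on galGal3 was not used here, since the gene table at hand was of another assembly. Regions are therefore given by position, and neither the part of the rule that names genes nor the planned tests of gene lists was applied.

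Alternatives fixed before the data were examined were normexp with an offset of 50, the deposited value table, centring on autosomes, restriction to probes bright in the reference on all arrays, other call thresholds, other window sizes, other model terms, and leaving out each bird. Normexp was run on median spot signals, in place of the planned mean signals. The planned correction on probe base composition was not run, as probe sequences were not used here. Chosen after seeing the data were removal of the trend of log ratio on signal over 50 bins, window medians, calls on differences between birds, regions away from chromosome ends, adjustment over autosomes alone, the bounds for signals not well above background, autosomal centring together with leaving out each bird, and pairing over region windows without those that differ by sex.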

Results

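Genomic DNA from blood of 6 adult chickens was hybridised to a genome tiling array, each bird against the same female Dehong chicken. The test birds were a female and a male of each of 3 breeds: white Leghorn, Cobb broiler and Dou. The comparisons asked where each bird differed in copy number from the Dehong female, and where the breeds and sexes differed from each other. Median test signals per array lay between 998 and 1054, and the array carried a probe about every 2234 bp on the autosomes and Z. Regions are given on the chicken build galGal3. Each slide held the female and the male of 1 breed, so breed and slide cannot be told apart between breeds, while the sexes were compared within slides.

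Males carried more Z signal and much less W signal relative to the female reference, in all 3 breeds. In chickens, males have a pair of Z chromosomes and females a Z and a W. The median log2 ratio of Z was 0.93 ± 0.01 in males (SD, n = 3) and -0.02 ± 0.01 in females (SD, n = 3), a difference of 0.94. On W it was -3.77 ± 0.11 in males and -0.05 ± 0.06 in females, a difference of -3.72. Autosomal medians differed between sexes by -0.01.

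The male and female medians did not overlap on either sex chromosome, and the exact two-sided permutation p was 0.1 for each, the smallest value that 3 against 3 birds allow. Within white Leghorn, Cobb broiler and Dou, each on 1 slide, the Z difference was 0.94, 0.94 and 0.95, and the W difference -3.77, -3.80 and -3.60. Of the 187 W probes, 59 were not well above background in any male. With such signals set to the lowest signal well above background on the same array, W was at least 12.6-fold lower in males. With normexp background correction the difference was -0.85 on W and 1.26 on Z, so the size of both depends on how background is handled.

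**Figure D1:**
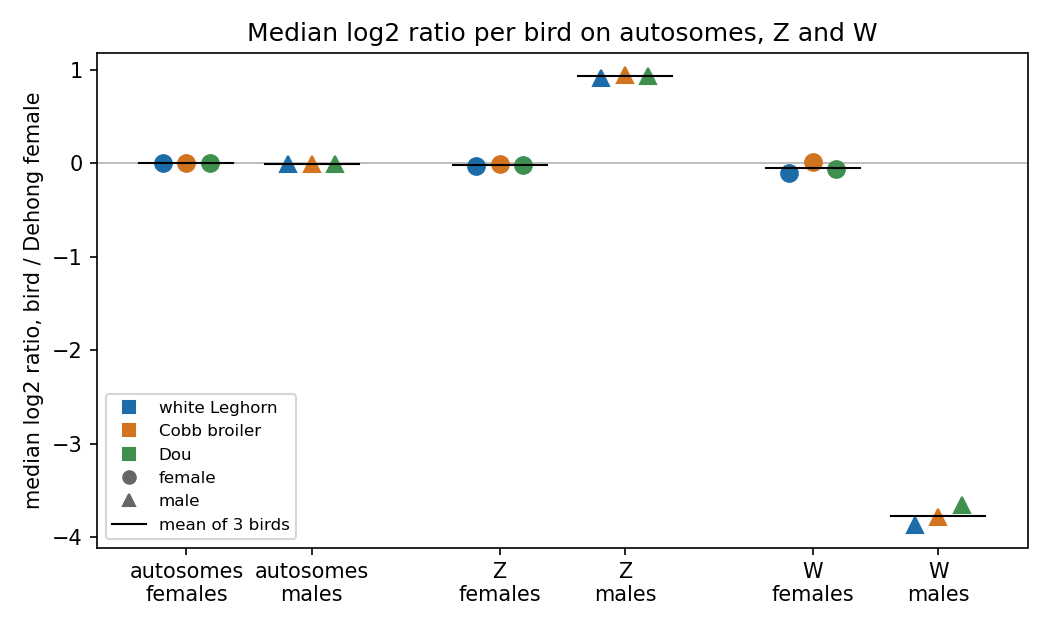
Median log2 ratio of each bird over the Dehong female on autosomes, Z and W, with colours for breeds, circles for females, triangles for males and a line at the mean of 3 birds. Males lie at 0.93 on Z and -3.77 on W on average, females near 0 on both.

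Nearly the whole of Z rose in males by a similar amount. Of 2561 Z windows, 2550 differed by sex in limma, 2549 of them higher in males, with a median effect of 0.92 and quartiles of 0.87 and 0.96. The exception in direction, chosen after its values were seen, lay on chromosome Z from 73499010 to 73550495, where males fell by 0.70 (adjusted p = 0.000206), at -0.64 ± 0.06 in males and 0.05 ± 0.09 in females (SD, n = 3 each). Of its 10 probes, 1 was not well above background in any male, which makes the window at least 1.49-fold lower. The run on chromosome Z from 49416101 to 68441105 was at 0.92 with all birds, and at 0.92 but no longer passing throughout without the female or the male white Leghorn (largest adjusted p = 0.0681). On W, 16 of 18 windows differed, all lower in males.

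A few autosomal places also differed by sex, most of them lower in males with all 6 birds. The largest was on chromosome 1 from 165871707 to 166014789, where 3 adjacent windows were at least 6.26-fold lower in males (largest adjusted p = 2.94e-05), as 10 of their 30 probes were not well above background in any male. Within it, the copy number region from 165883954 to 165976460 was called as a loss in all 3 males, while the females lay between -0.03 and 0.01. There 8 of 18 probes were not well above background in any male, so the region was at least 15.6-fold lower in males, with no measured size. With normexp the males' mean was -0.92. On the same chromosome from 60470146 to 60518048, males were higher by 0.64 ± 0.04 (SE), and the copy number region inside, from 60484102 to 60514786, was called as a gain in all 3 males at 0.79 ± 0.04 (SD, n = 3). Further runs lower in males lay on chromosome 2 from 95616006 to 95687692 (-0.76) and chromosome 1 from 152696020 to 152749655 (-0.75), which became -0.11 and -0.10 with window medians and no longer passed. The run on chromosome 2 also failed to pass with normexp (-0.19) and with autosomal centring (-0.74).

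In total, 68 of 37671 autosomal windows differed by sex with adjustment over all windows, 6 higher and 62 lower in males. This threshold corresponded to an unadjusted p of 0.00322, at which 121 autosomal windows would pass with no sex effect at all. Adjusted over autosomes alone, 7 windows passed, 1 higher and 6 lower. Of the runs named above, that of chromosome 1 at 165871707 then had an adjusted p of 0.00138, and the others of 0.0954 (60470146), 0.872 (95616006) and 0.119 (152696020). The count was 110 without the female or the male white Leghorn (34 higher, 76 lower), 141 without the female or the male Cobb broiler (51 higher, 90 lower), 132 without the female or the male Dou (21 higher, 111 lower), 113 with normexp (7 higher, 106 lower) and 36 with window medians (11 higher, 25 lower). With breed in the model, a bird left without its partner adds nothing to the sex test. Leaving out either bird of a breed therefore gave the same count, from the sexes in the other breeds alone. With autosomal centring and without the female or the male Cobb broiler, a pair of choices made after seeing the data, 136 windows passed, 65 higher and 71 lower.

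**Figure D2:**
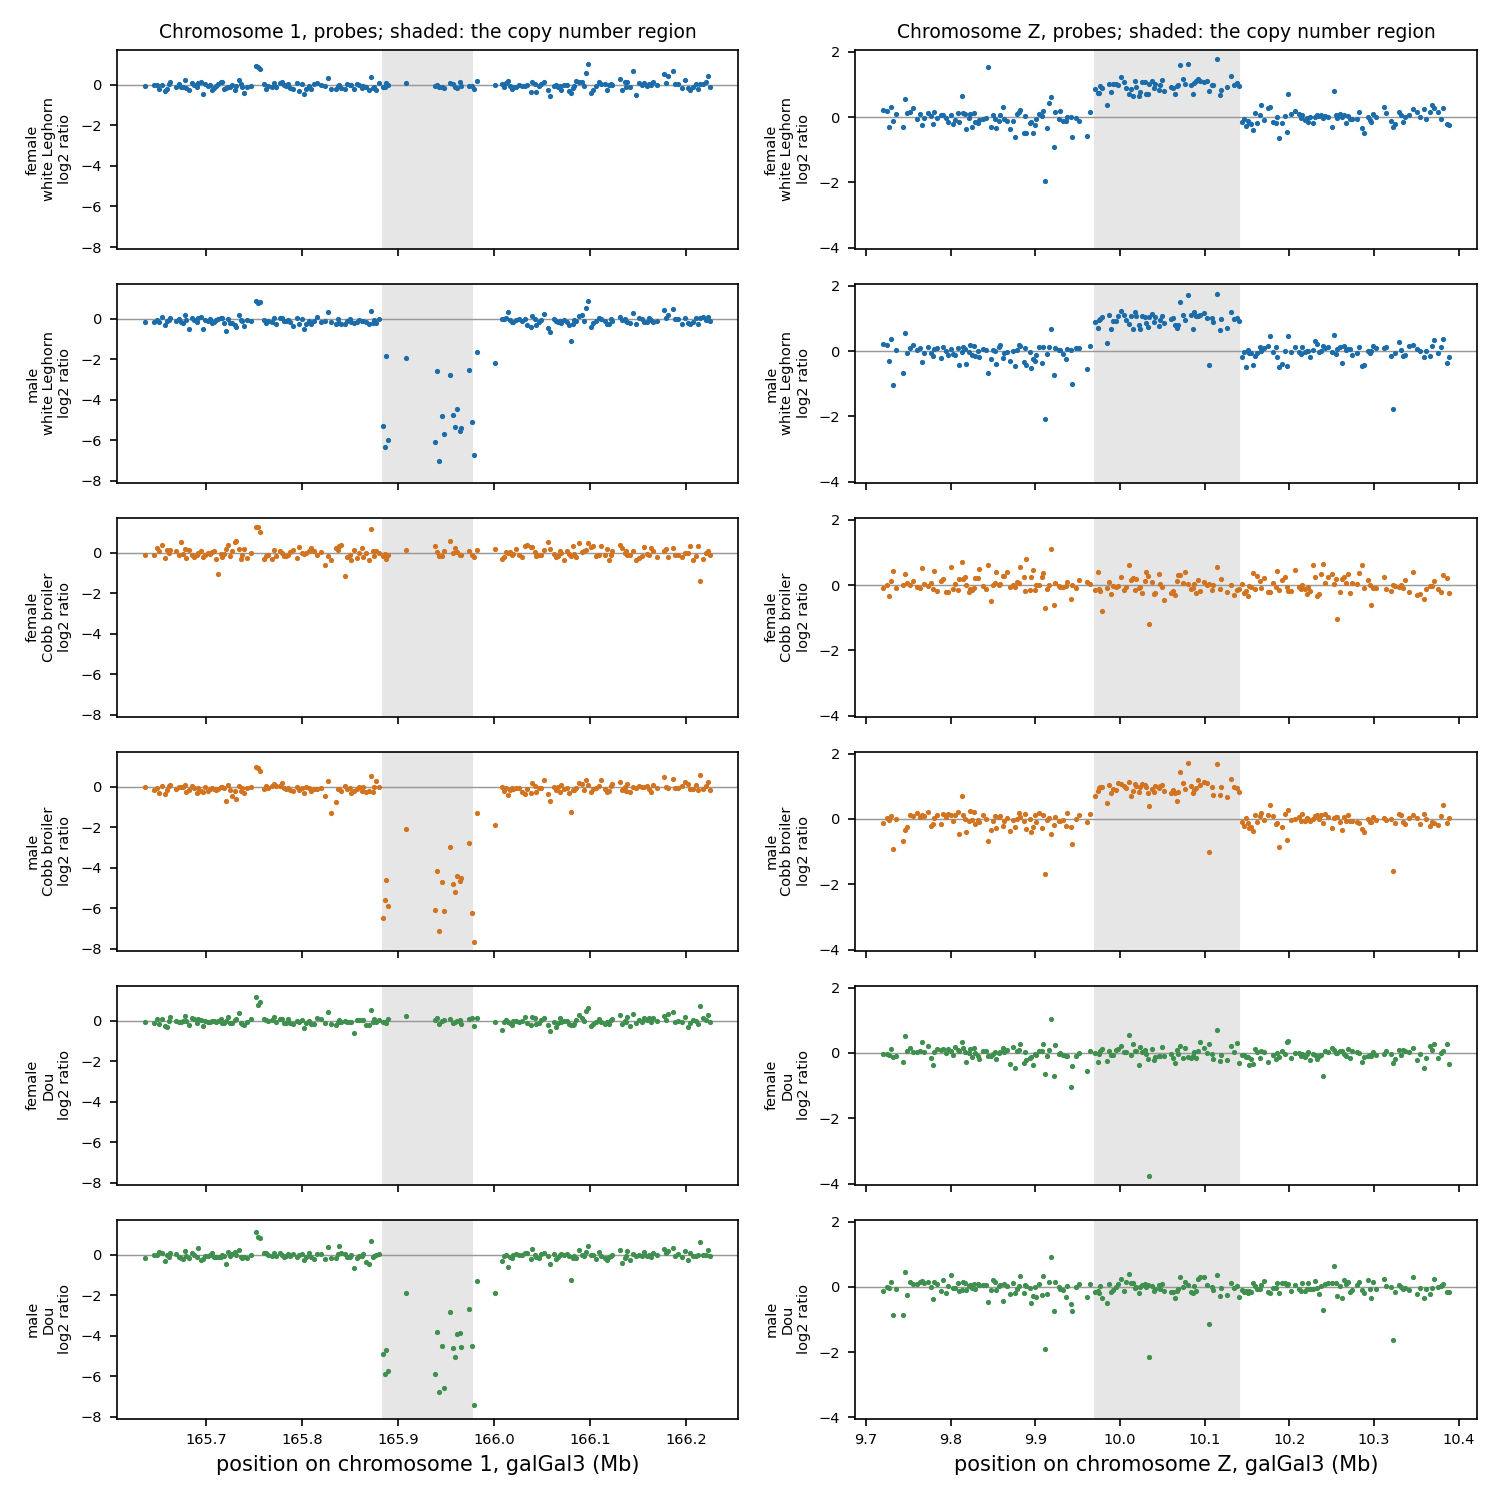
Log2 ratio of single probes over the Dehong female against position on galGal3 (Mb), per bird, around the copy number regions on chromosome 1 (left) and chromosome Z (right, after centring each array on its Z median), which are shaded. The 3 males lie far below 0 in the first, where 8 of 18 probes were not well above background in any male, and both white Leghorns and the male Cobb broiler at 0.95 in the second.

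Segmentation gave 214 gains and 236 losses over the 6 birds, which merged into 279 copy number regions. The female white Leghorn had 31 gains and 45 losses and the male 30 and 60. The female Cobb broiler had 50 gains and 21 losses, and the male Cobb broiler 41 and 38. In Dou, the female had 27 gains and 43 losses and the male 35 and 29. Losses within 100 kb of a chromosome end made up 19 of the female white Leghorn's 45 and 17 of the female Dou's 43. Away from the ends the gains and losses numbered 30 and 26 in the female white Leghorn, 29 and 50 in the male, 25 and 26 in the female Dou, and 204 and 182 over the 6 birds. These counts compare single birds with the Dehong female, with no replicate hybridisation, so no test between groups was made.

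The regions covered 6.80 Mb, or 0.662% of the probed span of the autosomes and Z, with a median length of 15.3 kb and a range of 6.20 to 314 kb. There were 143 gain regions, 132 loss regions and 4 with both, 254 on autosomes and 25 on Z. Most, 197, were called in 1 bird, and 10 were called in all 6. A call in 1 bird alone does not show that the others lack the change. Examples chosen after their values were seen went both ways. On chromosome 1 from 104503805 the male Dou was called at 1.37. Both white Leghorns, the male Cobb broiler and the female Dou had uncalled values there between 1.53 and 1.78. On chromosome 1 from 118031006 the female Cobb broiler was called at 1.25, and the other birds lay between 0.03 and 0.20. With normexp, 284 gains and 580 losses made 543 regions, 199 of gain and 337 of loss.

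**Figure D3:**
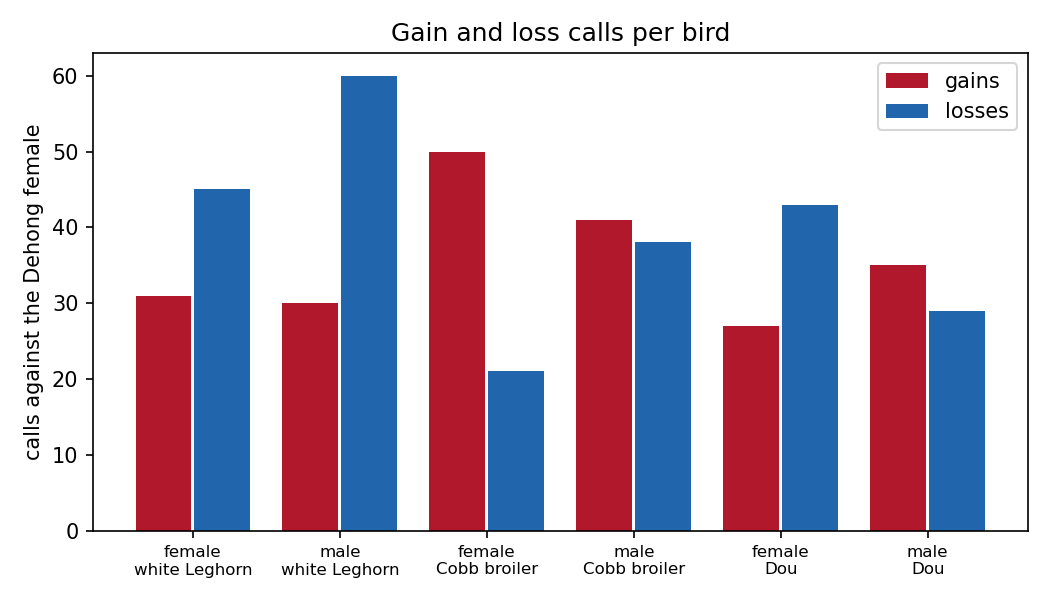
Number of gain (red) and loss (blue) calls in each bird against the Dehong female. Gains range from 27 in the female Dou to 50 in the female Cobb broiler, and losses from 21 in the female Cobb broiler to 60 in the male white Leghorn.

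The longest Z gain was shared by birds of different breeds. On chromosome Z from 9969845 to 10140048, 61 probes over 170 kb averaged 0.95 ± 0.02 (SD, n = 3) in both white Leghorns and the male Cobb broiler. The other 3 birds lay between -0.07 and -0.03. These values are relative to each array's own Z median.

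Short regions with large ratios were carried by several breeds. On chromosome 13 from 734196 to 747478, the female white Leghorn (1.79) and female Dou (1.82) were called as gains, the male white Leghorn, male Cobb broiler and male Dou had uncalled values of 1.39, 1.39 and 1.73, and the female Cobb broiler had 0.11. On chromosome 10 from 7166220 to 7174703, both white Leghorns were called at 1.77 ± 0.11 (SD, n = 2), and both Dou birds had uncalled values of at least 1.37. On chromosome 4 from 52065734 to 52077869, gains in both white Leghorns and the female Dou averaged 1.47 ± 0.21 (SD, n = 3). There the female Cobb broiler and male Dou had uncalled values of 0.72 and -0.06, and the male Cobb broiler had -0.64. In this region 1 of 6 probes, and in the chromosome 10 region 1 of 5, was not well above background in at least 1 bird. A loss on chromosome 4 from 89627586 to 89648936 averaged -0.97 ± 0.05 (SD, n = 3) in both white Leghorns and the male Cobb broiler. The chromosome 10 and 13 regions rested on 5 probes each, and the mean of the chromosome 10 region was 0.61 over probes bright in the reference and 0.81 with normexp.

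At 9 regions, 4 of gain and 5 of loss, calls in the same direction were made in all 6 birds. The losses included chromosome 1 from 44984123 to 45064556, at -0.73 ± 0.05 (SD, n = 6) over 33 probes, chromosome 2 from 12385227 to 12407681 at -0.88 ± 0.04, chromosome 3 from 107786756 to 107819370 at -0.59 ± 0.15, and chromosome 5 from 3104188 to 3113762 at -0.83 ± 0.07. The gains were on chromosome 1 from 167926654 to 167956574 at 0.83 ± 0.06, chromosome 2 from 86319269 to 86335948 at 0.76 ± 0.14, chromosome 4 from 19183231 to 19196600 at 0.69 ± 0.08, and chromosome 27 from 182014 to 386671 at 0.59 ± 0.09. With no dye swap, a difference common to all arrays cannot be told apart from a dye bias at those probes.

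Each breed had regions called in both of its birds and in no other breed: 12 in white Leghorn, 5 in Cobb broiler and 8 in Dou. In white Leghorn these were 7 gains and 5 losses, among them gains on chromosome 1 from 184868613 to 184885052 at 0.99 ± 0.01 (SD, n = 2), chromosome 2 from 73252349 to 73272906 at 0.85 ± 0.04 and chromosome 2 from 130453299 to 130473299 at 0.66 ± 0.25. On chromosome Z from 66121528 to 66132751 the white Leghorns were at -0.84 ± 0.08, but the male Cobb broiler and female Dou had uncalled values of -0.57 and -0.50.

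In the Cobb broilers, a gain on chromosome 1 from 48010310 to 48038759 averaged 0.97 ± 0.14 (SD, n = 2), a gain on chromosome 1 from 152966119 to 152997967 averaged 0.71 ± 0.19, and losses on chromosome 11 from 2674301 to 2687093 and chromosome 2 from 36499780 to 36511022 averaged -1.13 ± 0.08 and -0.92 ± 0.18. In the chromosome 11 region the male Dou had an uncalled value of -0.42. Their remaining region, on chromosome 1 from 191155314 to 191179082, was a gain in the female (0.50) and a loss in the male (-0.35), with uncalled values of -0.24 and -0.41 in the female and male white Leghorn.

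Of the Dou regions, 7 were gains and 1 was a loss. The gains included chromosome 17 from 1286050 to 1312499 at 0.60 ± 0.02 (SD, n = 2), chromosome 13 from 3970499 to 3989934 at 0.79 ± 0.28, chromosome 9 from 21948228 to 21960037 at 0.75 ± 0.32 and chromosome 1 from 199639591 to 199679142 at 0.49 ± 0.12, where the female and male white Leghorn had uncalled values of 0.34 and 0.33. On chromosome 1 from 156585268 to 156595314 the Dou birds averaged 0.77 ± 0.27, while the male white Leghorn and male Cobb broiler had uncalled values of -0.95 and -0.96. In that region 1 of 6 probes was not well above background in at least 1 bird, and no bound was computed. Another of these gains, chosen after its values were seen, on chromosome 3 from 85859867 to 85896252, lay between 0.35 and 0.50 in all 6 birds. Being called in 1 breed alone does not show a difference between breeds, which the window test addressed.

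Among the longest regions, 1 on chromosome 27 from 477458 to 791787 spanned 314 kb and was carried by the male Cobb broiler at 0.72, with 0.10 over the whole region in the female white Leghorn, which was called in part of it. On chromosome 16, which carries the chicken major histocompatibility complex, the region from 193489 to 352976 was at 0.60 and 0.76 in the female and male Cobb broiler and between 0.05 and 0.16 in the others. Calls within it differed between birds: the male Cobb broiler was at 1.81 from 247575 to 342967, and the female Dou alternated between gains at 0.44 and 0.52 and losses at -0.54 and -0.83. A loss at the end of chromosome 11, from 21805570 to 21924074, was called in the female white Leghorn and the female Dou at -0.40 ± 0.04 (SD, n = 2), and the other birds lay between -0.39 and -0.22.

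**Figure D4:**
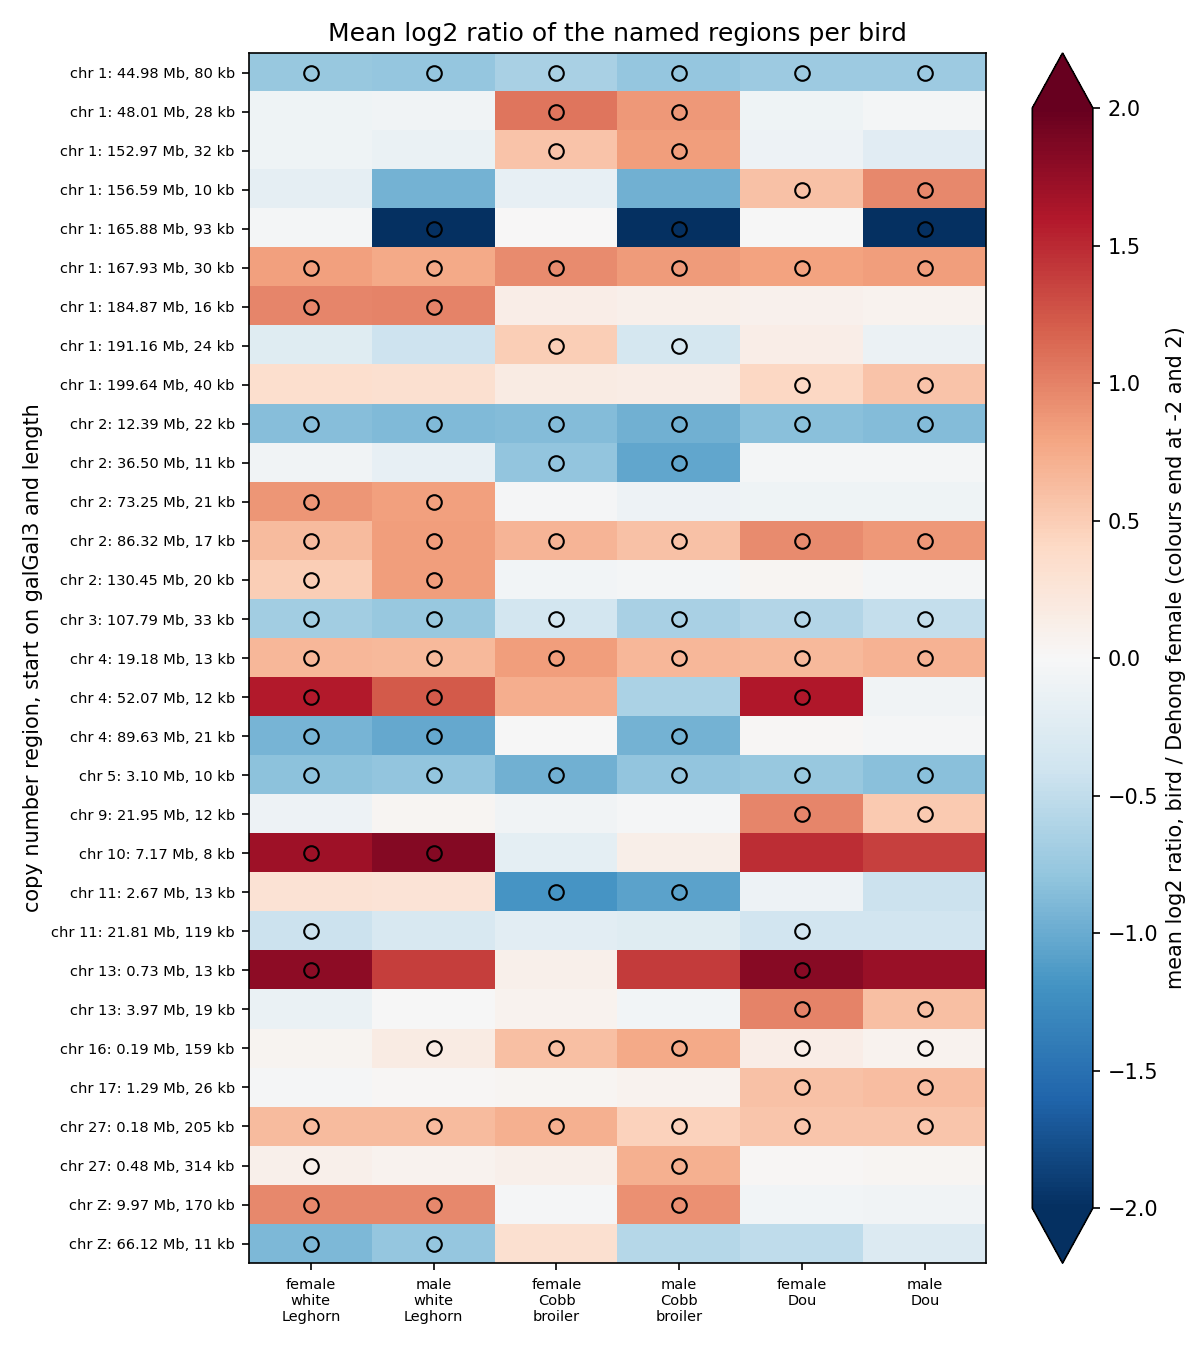
Mean log2 ratio of each bird over the Dehong female (colour, ending at -2 and 2) in the regions named by the fixed rule, labelled by start and length on galGal3, with circles for birds in which a call was made. Z regions are after centring on each array's Z median, and the lowest values are the 3 males on chromosome 1 from 165883954.

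Birds of a breed shared more calls than chance placement gave, and so did birds of different breeds. On autosomes, pairs of the same breed shared 21 to 35 calls and pairs of different breeds 15 to 29, against at most 4 in any of 1000 circular shifts. In relation to the pair member with fewer calls, this was 31.8% to 48.6% and 22.7% to 42.0%. A variant of the common reference bird appears in all 6 comparisons and adds to this sharing. Calls made on the difference between birds, in which the reference cancels, numbered 40 in the white Leghorn pair, 44 in the Dou pair, 130 in the Cobb broiler pair and 64 to 132 between breeds.

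On average over the 3 breeds, autosomal profiles were closest within breeds, but the Cobb pair was not close. Each breed pair was also the pair that shared a slide, so resemblance within breeds cannot be told apart from resemblance within slides. The mean squared difference of autosomal window values was 0.00767 in the white Leghorn pair, 0.00805 in the Dou pair and 0.0221 in the Cobb broiler pair, against 0.0178 between the female Cobb broiler and the male Dou and 0.0125 between the males of these breeds. The mean of the 3 breed pairs was 0.0126, the lowest of the 15 ways to form 3 pairs, whose median was 0.0161 (exact one-sided permutation p = 0.0667, the smallest possible). The order did not hold inside copy number regions, where 9 pairings were lower (exact p = 0.667). Over region windows that did not differ by sex, chosen after seeing the data, the exact p was 0.0667. Over all autosomal windows it was 0.267 without the female white Leghorn, the male white Leghorn or the male Dou, and 0.333 without the female Dou.

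Few windows passed the tests among breeds, and most stood alone. In simulated windows the breed test recovered 0% of those changed by 0.3 in Dou, 23.4% at 0.6 and 62.9% at 1. A low count therefore does not show that the breeds differ at few places. In limma, 126 of 40232 autosomal and Z windows passed the F test among breeds, against 4270 at an unadjusted p under 0.05, and 14 of them (11.1%) lay in copy number regions. Dou differed from white Leghorn in 132 windows, 70 higher and 62 lower. Cobb broiler differed from white Leghorn in 67, 49 higher and 18 lower, and Dou from Cobb broiler in 35, 7 higher and 28 lower. At least 5 of the 10 probes differed by over 0.5 times the window's effect in 9 of the 132, 11 of the 67 and 1 of the 35 windows.

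Runs of at least 2 adjacent windows that differed between breeds included chromosome 14, where white Leghorns were lower. From 14989428 to 15029800, Cobb broilers were higher than white Leghorns by 0.97 ± 0.04 (SE, largest adjusted p = 0.0275), and from 14989428 to 15062170 Dou were higher by 0.83 ± 0.05 (largest adjusted p = 0.0243). On chromosome Z from 42966941 to 43022427, Dou exceeded white Leghorn by 1.05 ± 0.06 (adjusted p = 0.0387). On chromosome 1 from 200104375 to 200147444, Dou fell by 0.69 against white Leghorn (adjusted p = 0.0418) and by 0.86 against Cobb broiler (adjusted p = 0.0461), with both Dou birds between -0.74 and -0.72. None of these runs passed with normexp or window medians, and with the latter the Dou minus white Leghorn effect at 200104375 was 0.04. The chromosome 14 runs and the comparisons with white Leghorn on Z and chromosome 1 also lost the call without the female or the male white Leghorn, at effects of 1.01 and 0.94 for Cobb broiler and 0.86 and 0.81 for Dou on chromosome 14, 1.14 and 0.95 on Z, and -0.64 and -0.74 on chromosome 1. All the Dou runs lost it without the female or the male Dou, at 0.87 and 0.80 on chromosome 14, 1.10 and 0.99 on Z, and -0.67 and -0.70 against white Leghorn and -0.85 and -0.88 against Cobb broiler on chromosome 1. Those on Z and chromosome 1 also lost it with the signal trend removed (1.01 on Z, -0.70 against white Leghorn and -0.84 against Cobb broiler on chromosome 1).

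The counts of breed windows and their directions changed when single birds were left out. A bird left without its breed partner adds nothing to the residual spread. Leaving out either Cobb broiler therefore takes the Cobb pair, which was not close, out of that spread. No Cobb broiler enters the comparison of Dou with white Leghorn, so the change of that count without a Cobb broiler comes through the spread. Without the female or the male white Leghorn, 60 and 36 windows passed the F test, without the female or the male Cobb broiler 921 and 2923. For Cobb broiler against white Leghorn, the counts were 18 and 14 without the female and the male white Leghorn, 311 (155 higher, 156 lower) and 3968 (3387 higher, 581 lower) without the female and the male Cobb broiler, and 131 without the female or the male Dou. For Dou against white Leghorn they were 17 and 13 without the female and the male white Leghorn and 1086 without either Cobb broiler, and the direction turned without the female Dou (42 higher, 54 lower) or the male Dou (37 higher, 72 lower). Dou against Cobb broiler, the only breed comparison within a scan day, gave 310 windows without the female Cobb broiler, where the direction turned (170 higher, 140 lower), 551 without the male (135 higher, 416 lower), and 19 and 63 without the female and the male Dou. With normexp, 16 windows differed between Cobb broiler and white Leghorn, 9 higher and 7 lower. The direction also turned with window medians for Dou against Cobb broiler (4 higher, 2 lower) and in a model without sex for Dou against white Leghorn (16 higher, 18 lower).

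The mean of the 6 birds passed the test against the Dehong female in 101 autosomal windows, 54 higher and 47 lower, called shared windows here. Of these, 34 lay in copy number regions. A window could pass without a difference in each of the 6 birds. The longest run covered chromosome 27 from 142829 to 340973 at 0.73 ± 0.04 (SE, largest adjusted p = 0.0135), higher in 6 of 6 birds. For this and the runs below, SE and p rest on the spread among the test birds alone. All 6 were compared with DNA of the same Dehong bird, whose own spread is left out. With no dye swap, a change in that bird cannot be told apart from a dye bias at those probes. Other runs lay on chromosome 4 from 87380562 to 87432094 at 0.69 ± 0.03 (adjusted p = 0.0208), chromosome 1 from 44993309 to 45064556 at -0.74 ± 0.02 (adjusted p = 0.00379) and chromosome 17 from 11122736 to 11171729 at -0.58 ± 0.03 (adjusted p = 0.0070), each in the same direction in 6 of 6 birds. A run on chromosome 1 from 165871707 to 166014789 was carried by the 3 males alone, has only a bound there as given above, and did not pass with normexp (-0.37).

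The run on chromosome 27 was at 0.64 over probes bright in the reference and at 0.36 with window medians, and passed with neither. The run on chromosome 4 was at 0.30 over probes bright in the reference and at 0.10 with window medians, and likewise passed with neither. It also lost the call without the female or the male white Leghorn, at 0.69 and 0.70. The count of shared windows was 243 without the female Cobb broiler, with the direction turned (97 higher, 146 lower), 129 without the male Dou (63 higher, 66 lower), 190 without the male Cobb broiler (97 higher, 93 lower), 174 with normexp (66 higher, 108 lower), 68 over probes bright in the reference (23 higher, 45 lower), 43 with window medians (7 higher, 36 lower), 36 with 20 probes per window (15 higher, 21 lower) and 11231 with no fold threshold (4751 higher, 6480 lower).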

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

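The tests of false calls, of W copies and of how many probes carry a window, and the counts over other splits of the birds, were chosen only after the results were seen, as was the look at sequence outside the assembled chromosomes. Signal that differed by sex appeared in such sequence, which the comparisons above did not use. Of 7979 probes on unplaced sequence, 58 were lower in males, with a median of -1.04, and 18 were higher, with a median of 0.89. On unordered sequence assigned to chromosome 20, 14 of 18 probes were lower in males, with a median of -4.36, and 4 of the 14 were not well above background in any male. On unordered Z sequence, 83 of 110 probes were higher in males (median 0.93) and 3 were lower.

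Splitting the 6 birds 3 against 3 in every way gave 10 splits, of which 1, the real one, gave as many windows. It called 2550 windows on Z, 16 on W and 68 on autosomes, against at most 0 in any other split. With 10 splits no share under 0.05 is possible. For the autosomes this outcome was set beforehand, since the Z windows relax the shared threshold in the real split alone, and it says nothing about those windows.

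The 62 autosomal windows lower in males were weighed further. False calls let in by the adjustment over Z have no direction. With autosomal centring 10.71% of the 56 passing windows were higher in males (6 windows, 95% binomial interval 5.00% to 21.5%). The share was 36.0% of 111 without the female or the male white Leghorn (27.7% to 45.3%). Without the female or the male Dou it was 22.3% of 121 (15.8% to 30.5%). Without the female or the male Cobb broiler it was 47.8% of 136, with an interval that includes an even split (39.6% to 56.1%). Such calls therefore stay open, except for the 6 lower windows that passed when adjusted over autosomes alone. At least 5 of 10 probes lay below 0.5 times the window's effect in 7 of 55 single windows. In each of 1000 draws with an even change of the same size at least 50 did, so fewer probes carried most single windows. Among windows in runs this held for 3 of 7, against at least 6 in each draw. The draws argue against an even change over the windows in runs as a set. With 7 windows, the share carried by few probes stays open for the runs. Over the 104 probes below -0.5 in these windows, which were picked for the difference, the female mean had a median of -0.0472 and quartiles of -0.223 and 0.188, going both ways, and the males a median of -2.04. The W probes themselves had SDs over probes of 0.236, 0.233 and 0.192 in the female white Leghorn, Cobb broiler and Dou. Female values on both sides of 0 therefore do not speak against sequence similar to, or belonging to, the W chromosome, which males lack. Such sequence stays open as a candidate explanation that this test does not decide, and a sex difference on the autosomes themselves was not tested.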

How the results depend on the processing

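The bounds for dim signals, autosomal centring without single birds, removal of the signal trend, window medians, differences between birds, adjustment over autosomes alone, pairing over region windows without sex differences and the distance from chromosome ends were chosen after seeing the data; the rest were fixed before. Of the alternatives for the values that answer a comparison, 143 were counted as the same, 90 as moved and 1 as reversed. For the Z and W sex differences, the same meant the same direction, whatever the size. For the breed pairing, it meant that the breed pairs stayed below the median pairing. Counts were the same if their totals stayed within 1.5 times, even where the balance of higher and lower windows turned, as given above. Z (0.94) and W (-3.72) sex differences ranged from 0.94 to 0.95 and from -3.78 to -3.67 without single birds, and were 1.26 and -0.85 with normexp. Where not said otherwise the cause was not tested. Other window sizes and probes per call, and fewer birds for calls and regions, change counts by construction.

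Gains numbered 110 at a mean of 0.6, 556 with 3 probes, 60 with 10 probes and 114 at a z score of 10. Losses numbered 580 with normexp, 401 and 110 at means of 0.25 and 0.6, 674 and 73 with 3 and 10 probes, and 92 at a z score of 10. Regions numbered 543 with normexp, 131 at a mean of 0.6, 774 and 67 with 3 and 10 probes, 433 and 101 at z scores of 5 and 10, and 563 from differences between birds. Without single birds there were 164 to 187 gains, 176 to 215 losses and 237 to 258 regions.

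For Z, W and autosomes, sex windows numbered 22031, 158 and 728 with single probes, 5046, 33 and 180 with 5 probes, and 1279, 8 and 29 with 20 probes. Autosomal sex windows numbered 113 with normexp, 36 with window medians, 7 adjusted over autosomes alone, 110 to 141 without single birds, and with autosomal centring too 111 without a white Leghorn, 136 without a Cobb broiler and 121 without a Dou; on Z that range was 2550 to 2557, and on W 16 to 16.

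Among breeds (F test), Cobb broiler against white Leghorn, Dou against white Leghorn and Dou against Cobb broiler, normexp gave 23, 16, 18 and 4 windows, single probes 509, 288, 713 and 165, 5 probes 245, 111, 282 and 102, window medians 12, 7, 10 and 6, and a model without sex 1, 1, 34 and 0, with 3467, 3627, 3717 and 2516 at an unadjusted p under 0.05 in limma. With 20 probes, 66 windows passed the F test, 52 Dou against white Leghorn and 23 Dou against Cobb broiler. Without single birds the ranges were 36 to 2923, 14 to 3968, 13 to 1086 and 19 to 551. Windows shared by all 6 numbered 174 with normexp, 6179 with single probes, 416 and 36 with 5 and 20 probes, 43 with window medians, 11231 with no fold threshold and 89 to 243 without single birds.

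The exact p of the breed pairing was 0.667 inside copy number regions, where other pairings were closer, and 0.0667 to 0.333 without single birds. The mean at chromosome 1 from 191155314 became -0.35 without the female Cobb broiler, the carrier of the gain, and 0.50 without the male, the carrier of the loss, and the Dou minus white Leghorn effect at chromosome 1 from 200104375 became 0.0399 with window medians. Among named regions 228 alternatives stayed within their spread and 28 moved; among runs 186 kept the call and 41 lost it. Without a bird, its partner is assumed to vary like the other breeds, and the partner adds nothing to the sex test of windows. The base composition correction and the gene list alternatives were not run. A slide block is the same as the breed term, and without it 2530, 16 and 67 windows differed by sex on Z, W and autosomes. Signals were well above background for at least 99.8% of spots in each channel, but in no male for 59 of 187 W probes and 8 of 18 in the chromosome 1 region from 165883954. With each male's signals below that at the lowest signal well above background, the W difference was -3.66 and the region's mean in males -3.98.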

Other observations

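The tests on the female Cobb broiler array, and those of base composition and of the Dehong bird at chromosome ends, were chosen only after the results were seen. Of 563 regions called on differences between birds (13.9 Mb), 140 overlapped a region called against the Dehong female. Of the 10 regions called in all 6 birds, 7 overlapped no difference between birds. Near the end of chromosome Z, the window from 73467825 to 73495074, beside the one lower in males, differed by 0.23 (adjusted p = 0.119), well under the median of 0.92 on Z.

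The female Cobb broiler stood apart from its breed partner. Over autosomal windows its profile correlated with that of the male Cobb broiler at 0.352, and with those of the female and male Dou at 0.369 and 0.441, against 0.749 within white Leghorn and 0.694 within Dou (across windows, which are not independent). Over windows of 20 probes the Cobb pair stayed at 0.363. The white Leghorn pair did not rise with wider windows either, at 0.754 with single probes and 0.751 with 20 probes. This test therefore cannot decide on higher probe noise. With the relation of log ratio to signal removed the Cobb pair was at 0.395, so that relation alone was not the whole cause. This array was still the only one whose dim probes clearly exceeded bright ones (0.28 against -0.16 to 0.00 in the others). A mislabelled bird cannot be told apart from a true difference between the birds: 31.8% of its 66 autosomal calls were shared with the male Cobb broiler (95% binomial interval 21.8% to 43.8%), against at most 27.3% with another bird. The bound for that test was tightened after its value was seen, since the first only asked for the highest share, which was met by 3 calls. In the other direction, 29.2% of the male Cobb broiler's 72 autosomal calls were shared with the female Cobb broiler. That was less than with the male white Leghorn (36.1%), the female white Leghorn (31.9%) or the male Dou (30.6%). It was more than with the female Dou (25%).

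Log ratios were lower near chromosome ends, where 23 loss regions and 4 gain regions lay within 100 kb. Windows there were lower than those over 1 Mb away by -0.11 ± 0.04 (SD, n = 6), below 0 in 6 of 6 birds, and the difference was -0.12 with the relation to signal removed, which argues against that relation. Base composition is a candidate explanation: far from ends, the small chromosomes 21 to 28 were lower than chromosomes 1 to 10 by -0.0262 ± 0.0191, in 6 of 6 birds, though only by -0.002 in the male Cobb broiler. More copies of end sequence in the Dehong female, with a difference of -0.11, cannot be told apart from a dye bias, as no dye swap was made.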
